A study of Homo sapiens with 8 samples.

How the data were processed

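Repeat transcripts were measured by RNA sequencing in 8 samples of HCT116 cells, and 4 of them, 2 siControl and 2 siTIP60 libraries, entered the refit. The submitters' processing notes name hg19, Bowtie and Trimmomatic, without versions. How reads were assigned to repeat subfamilies, what was filtered and how library totals were set are not given in the sources used here. Reads of related subfamilies can align to each other's copies, so values of close relatives, such as the SVA or L1PA subfamilies, are uncertain to that extent. The files gave no coordinates, and none are given.

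The authors deposited a table of log2 normalized counts for 1116 repeat subfamilies and a table of log2 fold changes with FDR values (adjusted p-values) for siControl against siTIP60 and DMSO against JQ1. Per the file headers, each row of the second table also has a repeat class and family. The base and depth of the deposited log2 values were worked out from the values. In every library used, the linear value was an offset of 0.0433, common to the libraries, plus whole multiples of 1 step per library, and 100% of values came out whole within 0.01 read. The step was read as 1 read on the CPM scale of an effective library total, which gives the read numbers and totals in the report. The linear levels given as CPM have the offset taken off. No replicate pair agreed within sampling noise: chi-square per degree of freedom was 155.5 between the siControl libraries and 60.9 between the siTIP60 libraries. Rows with many reads weigh most in chi-square. The ribosomal row LSU-rRNA_Hsa stood at 34928 and 8071 CPM in siControl, and at 24885 and 15145 in siTIP60. Over all rows the order was the other way. The median absolute log2 difference was 0.134 in siControl and 0.204 in siTIP60, and the Pearson correlation of log2 values 0.983 and 0.974.

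Columns were matched to samples by their headers. The 2 columns headed siC went to siControl. The 2 columns headed siK went to siTIP60, because TIP60 is an older name of KAT5 and no other siRNA apart from the control is named in the labels. The 4 further columns of values, headed DMSO and JQ1, each fit more than 1 sample, with and without the control siRNA. The comparisons of JQ1 with DMSO set out on library values, with their lists and named subfamilies, were first fitted with these columns assigned by column order, which identifies no sample. Those fits were seen and then withdrawn, no reported value uses the 4 columns, and JQ1 is described from the authors' deposited table. The deposited log2 fold changes of siControl and siTIP60 ran opposite to siTIP60 minus siControl in the table of values, so their sign was turned. The JQ1 columns were turned likewise, from the same order of names in the header; this sign was taken from the naming and is an assumption.

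The 1096 subfamilies that varied among the 4 libraries were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trended prior) on the deposited log2 values, siTIP60 minus siControl, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2 scale with the authors' offset, which understates changes of rare subfamilies. Lists were tested with camera at a preset correlation of 0.01 on the same design and adjusted over 53 lists: 19 defined by name and 34 classes or families with at least 5 rows. The 53 held 47 distinct lists, since some names and families cover the same rows. A list needed 3 members, which left out HERV-W with 2. Alternatives were camera with an estimated correlation and fry. The list medians under JQ1 were set among 10000 random lists matched on mean level in the siRNA libraries, as a description without a p-value. The random lists were drawn without regard to relatedness, so ranks among them can overstate how unusual a list of relatives is. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

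The named subfamilies were fixed by rule before the data were examined: among those past the test whose groups did not overlap and whose mean lay above the table's lower quartile, the 12 largest rises and 8 largest falls (2 existed), plus 17 preset names, all measured. SVA_A, SVA_B, SVA_C and SVA_E, LTR12D, LTR7Y, MLT2B3, ERV3-16A3_I-int and HERVE-int are named as examples of lists after their values were seen, SVA_B also by the rule.

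The alternatives set in advance were median centring, quantile normalization, leaving out the lowest 25% by mean, adding 1 on the linear scale, constant and robust priors, a log2 change over 0.5 as a further condition, and leaving out each library in turn. Rows were chosen on the deposited values before any rescaling, because rows without reads otherwise gain false variation. Chosen after seeing the data were voom weights on the recovered reads (rows with at least 10 reads), a term for the library of each group with more ribosomal RNA, the same term with the siTIP60 libraries exchanged, and scaling to repeat reads without ribosomal RNA. The repeat-read total is made of the rows under test, so a rise of classes with many reads lowers every change on that scale.

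The fit was tested on simulated data drawn at the real means, depths and replicate spread, with the highest spreads capped, over 1081 subfamilies, 200 of them changed. For siTIP60 against siControl it recovered 33.3% of 1.5-fold, 69.0% of 2-fold and 92.1% of 4-fold changes, and 8 of 137 calls were unchanged rows. The real data gave 25 calls among 1096, so the adjusted threshold was stricter there. Recovery at the real threshold would be lower than these shares. With no list shifted, 0 lists passed camera. The simulated subfamilies varied independently, so this does not show how camera fares when members of a list vary together. For the same reason the share of unchanged rows among the calls may not hold for the real data.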

Results

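Transcripts of repetitive elements were measured by RNA sequencing in HCT116, a human colorectal carcinoma cell line. The labels name 8 samples. Cells received a control siRNA (siControl) or an siRNA against TIP60 (siTIP60), with 2 libraries a group harvested 72 h after transfection. TIP60, now named KAT5, is a histone acetyltransferase. The other samples were treated with the vehicle DMSO or with JQ1, an inhibitor of BET bromodomain proteins, which bind acetylated histones, with or without the control siRNA. Each of those conditions has 1 sample. The series title places the study around repression of endogenous retroviral elements by TIP60.

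The deposited table held log2 normalized counts for 1116 repeat subfamilies. It had no gene rows, so the level of the siRNA's own target, KAT5, is not analysed here and the knockdown was not checked. The siControl libraries, called a and b as names only, held 1546081 and 2072694 repeat reads, and the siTIP60 libraries 2100928 and 2020677. The linear values were read as CPM, counts scaled to the library total. On that reading the 4 effective library totals were 4477783, 6990972, 5746092 and 6191215, in the same order, and the repeat rows took 34.5%, 29.6%, 36.6% and 32.6% of them. Ribosomal RNA differed within each group. The LSU-rRNA_Hsa row stood at 34928 and 8071 CPM in the siControl libraries and at 24885 and 15145 in the siTIP60 libraries. Nothing in the labels says whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

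The first comparison asked which repeat subfamilies differed after TIP60 knockdown. Of 1096 subfamilies tested with limma, 23 rose and 2 fell at a Benjamini-Hochberg adjusted p under 0.05. Of the 23 that rose, 17 were long terminal repeat (LTR) elements, the class that holds endogenous retroviruses, against 568 of the 1096 tested (73.9% against 51.8%, odds ratio 2.68, 95% interval 0.999 to 8.37, two-sided Fisher's exact p = 0.0355). The interval does not exclude equal shares, and the test takes related subfamilies from the same 4 libraries as independent. LTR elements were 6 of 7 rises with each library centred on its median and 70 of 103 with a term for ribosomal RNA. With a constant prior they were 0 of 3 rises. The rises ranged from 0.55 to 2.17 on the log2 scale. At an unadjusted p under 0.05 there were 124 higher and 114 lower subfamilies, so the direction was uneven only among the strongest changes. The groups did not overlap in 614 subfamilies (56.0%, against 33.3% by chance). Subfamilies of the same 4 libraries vary together, so the share can stand well above 33.3% without an effect of the knockdown.

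Among the LTR subfamilies past the test, LTR58 rose most, from 4.62 ± 1.16 to 20.7 ± 2.22 CPM (SD, n = 2 in each group; log2 change 2.17 ± 0.31 SE, adjusted p = 0.0332), on 17 to 138 reads a library. HERVFH19-int, the internal part of a retrovirus, rose from 30.7 ± 3.05 to 100.3 ± 28.3 CPM (log2 change 1.68 ± 0.22 SE, adjusted p = 0.0307). LTR48B rose by 1.38 ± 0.19 and its relative LTR48 by 1.04 ± 0.19 on the log2 scale. LTR42 rose by 1.28 ± 0.19, MER52D by 1.26 ± 0.22, MER4A by 1.25 ± 0.14, MER70-int by 1.25 ± 0.21 and LTR10F by 1.13 ± 0.18, each with the SE of the limma fit. Of the 12 named rises, 3 were of other classes. Arthur1C, a DNA transposon, rose by 1.32 ± 0.23. L1M4c, an old L1 element, went from 824 ± 54.8 to 2069 ± 636 CPM (log2 change 1.29 ± 0.20 SE), and SVA_B from 169.9 ± 13.9 to 379.6 ± 16.2 (log2 change 1.16 ± 0.11 SE, adjusted p = 0.0156). The 2 falls were Tigger14a, a DNA transposon, from 324 ± 11.2 to 152.8 ± 39.1 CPM (log2 change -1.11 ± 0.17 SE, adjusted p = 0.0332), and L1PA11, a primate L1, from 284 ± 38.5 to 176 ± 2.91 (log2 change -0.68 ± 0.12 SE, adjusted p = 0.0457).

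All 25 calls kept their sign in every setting tried, but most were lost in several of them. The signs say little about stability. The groups did not overlap in any of the 25, so leaving out a library could not turn them. The priors, the size condition and the terms for ribosomal RNA leave the changes as they are. With a constant prior, which leaves the changes as they are, none of the 25 passed (LTR58 adjusted p = 0.122; 4 others did, 169 at an unadjusted p under 0.05). LTR48B went from 1.38 to 1.35 with each library centred on its median (adjusted p = 0.0537) and to 1.24 when libraries were scaled to their repeat reads without ribosomal RNA (adjusted p = 0.102). Centring left 7 of the 25, quantile normalization 9, and the repeat-read scale 0 in limma (242 at an unadjusted p under 0.05); that scale moved the median of all subfamilies from 0.017 to -0.12. Leaving out any 1 library left 1 residual degree of freedom and 0 calls in limma (108 to 289 at an unadjusted p under 0.05), so these fits say little about stability.

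**Figure D1:**
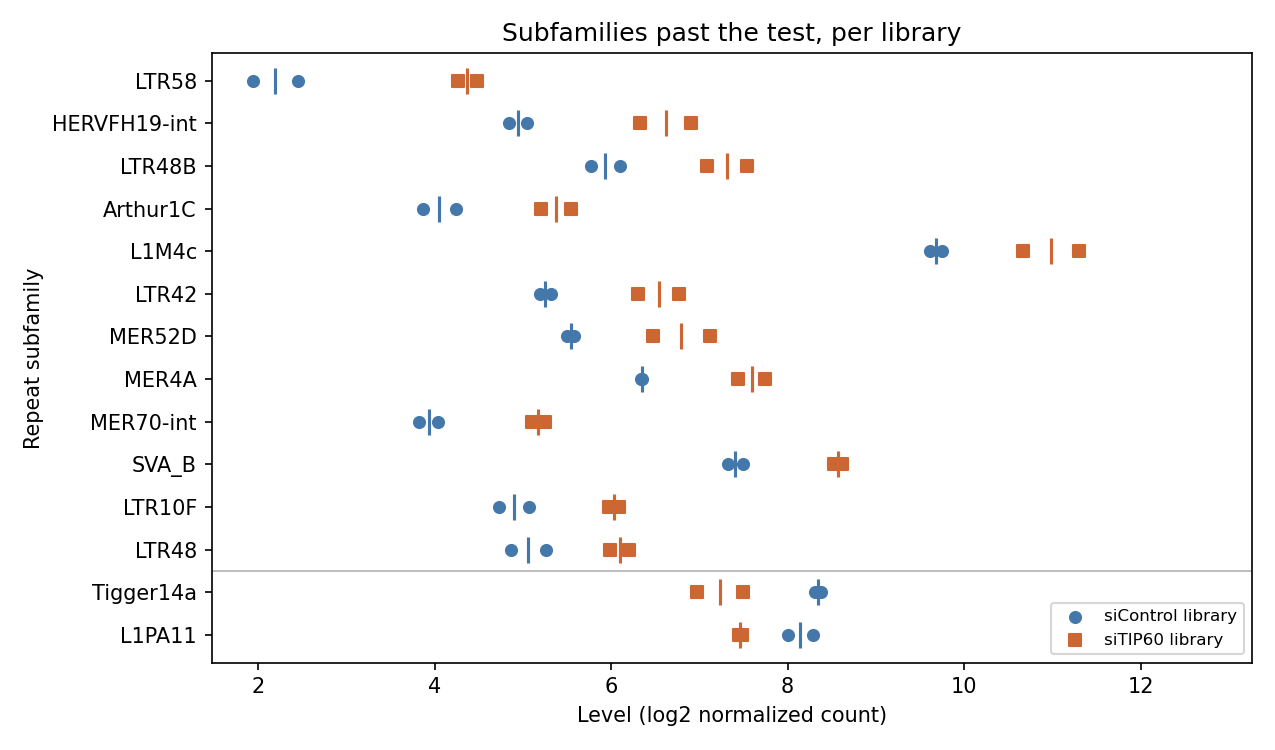
Level (log2 normalized count, x axis) of the 14 subfamilies named by rule in each siControl library (circles) and siTIP60 library (squares), with vertical ticks at the group means. The groups do not overlap in any of them, and the 2 below the line, Tigger14a and L1PA11, are lower in siTIP60.

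SVA elements are composite retrotransposons restricted to apes. All 6 SVA subfamilies were above 0 after TIP60 knockdown, with a median log2 change of 0.84, and 3 of them passed the test. SVA_B, SVA_C (0.82 ± 0.12 SE) and SVA_D (0.96 ± 0.15 SE) rose, and 3 did not pass over all rows. Adjusted over the list alone, 5 rose. SVA_E was at 0.85 (adjusted p = 0.0560), SVA_F at 0.80 (adjusted p = 0.109) and SVA_A at 0.28 (adjusted p = 0.284). The list passed camera (adjusted p = 8.01e-06), but not with an estimated correlation (adjusted p = 0.647 with an estimated correlation). SVA took 0.118% ± 0.00334 of the library total in siControl and 0.222% ± 0.0384 in siTIP60 (SD, n = 2).

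Over the whole LTR class, 345 of 568 subfamilies were above 0, with a median log2 change of 0.11 that turned to -0.02 when libraries were scaled to their repeat reads without ribosomal RNA. Of these, 17 rose, 0 fell and 551 did not pass, and 20 rose adjusted over the list alone. The class passed camera (adjusted p = 0.000212) but not with an estimated correlation (adjusted p = 0.647 with an estimated correlation). Without the siTIP60 library a its median was 0.070 and its camera adjusted p 0.0939. The ERVL family had a median of 0.18, which was 0.045 on the repeat-read scale, and 4 of its 121 members rose, among them MLT2B3 (0.63 ± 0.10 SE) and ERV3-16A3_I-int (0.80 ± 0.11 SE; camera adjusted p = 0.000940, and adjusted p = 0.647 with an estimated correlation). Without the siTIP60 library a the ERVL median was 0.085 and the camera adjusted p 0.0668, and without the siTIP60 library b the median was 0.28. The ERV1 family had a median of 0.12, which was -0.01 on the repeat-read scale, and 12 of its 293 members rose, among them HERVE-int (0.73 ± 0.12 SE; camera adjusted p = 0.0323, and adjusted p = 0.647 with an estimated correlation). The ERV1 camera adjusted p was 0.0580 without the siControl library b, 0.228 without the siTIP60 library a and 0.0655 without the siTIP60 library b.

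In the HERV9/LTR12 list, all 8 members were above 0 with a median of 0.40, which was 0.27 on the repeat-read scale. LTR12C rose by 0.55 ± 0.10 (SE, adjusted p = 0.0457), 7 did not pass, and 3 rose adjusted over the list alone. LTR12D was at 0.86 (adjusted p = 0.109) and HERV9-int at 0.27 (adjusted p = 0.456). The list's camera adjusted p was 0.00949, and adjusted p = 0.647 with an estimated correlation. Without the siControl library b 7 of 8 members were above 0 (camera adjusted p = 0.0706), and without the siTIP60 library a 6 of 8 (camera adjusted p = 0.208).

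The HERV-H list, whose LTR7 elements are known for their transcription in pluripotent stem cells, did not pass (camera adjusted p = 0.125, and adjusted p = 0.710 with an estimated correlation). Its 7 members had values above 0, with a median of 0.67 (0.42 after quantile normalization), and 0 passed singly, also adjusted over the list alone. One of them, LTR7A, had 8 reads in the siTIP60 library a and 0 in the other 3 libraries. HERVH-int stood at 6719 ± 2774 CPM in siControl and 11338 ± 6837 in siTIP60, and the groups overlapped. LTR7 stood at 807 ± 370 and 1587 ± 869, also with overlap. LTR7Y stood at 312 ± 142 and 706 ± 393, without overlap (log2 change 1.14 ± 0.42 SE, adjusted p = 0.193). The authors' deposited table called 1 HERV-H member higher, LTR7Y (FDR 0.0172), and 0 lower, with LTR7 at FDR 0.0506. The median of the list rested on single libraries. Without the siTIP60 library a the median was 0.059, with 4 of the 6 members left above 0 (camera adjusted p = 0.974), and without the siControl library b it was 0.24, with 5 of 7 above 0 (camera adjusted p = 0.551). Without the siControl library a it was 1.11 (camera adjusted p = 0.00935), and without the siTIP60 library b 1.33 (camera adjusted p = 0.00897). The HERV-K list did not pass (median 0.10, which was -0.03 on the repeat-read scale and 0.058 without the siTIP60 library b, camera adjusted p = 0.661, and adjusted p = 0.835 with an estimated correlation), with HERVK-int at -0.27 (adjusted p = 0.255) and LTR5_Hs at 0.16 (adjusted p = 0.446). The HERV-W pair of names was too small for a list test; HERV17-int was at 0.24 (adjusted p = 0.278) and LTR17 at 0.57 (adjusted p = 0.192). Of the other names fixed in advance, HERVL-int was at -0.21, MLT2A1 at -0.05, THE1B at -0.06 and MER41B at 0.23, and none passed.

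L1 elements are autonomous non-LTR retrotransposons. Of 131 L1 subfamilies 110 were below 0 and 21 above, and of the 2 past the test L1M4c rose and L1PA11 fell. In the young L1 list, which holds L1HS and the younger L1PA subfamilies, all 9 members were below 0 with a median of -0.38. None passed over all rows, and 7 fell adjusted over the list alone. L1PA2 stood at -0.36 (adjusted p = 0.176) and L1HS at -0.18 (adjusted p = 0.429). The list passed camera (adjusted p = 2.58e-05) but not with an estimated correlation (adjusted p = 0.647 with an estimated correlation). Of 88 mammalian L1 subfamilies 75 were below 0, with a median of -0.18, which was -0.32 on the repeat-read scale (camera adjusted p = 9.98e-07, and adjusted p = 0.647 with an estimated correlation); the only member past the test, L1M4c, rose. The TcMar-Tigger family of DNA transposons had a median of -0.23, which was -0.36 on the repeat-read scale, with 49 of 59 members below 0, of which Tigger14a fell (camera adjusted p = 1.40e-06, and adjusted p = 0.647 with an estimated correlation). Without the siTIP60 library a the mammalian L1 median was -0.10 and that of TcMar-Tigger -0.15, and without the siTIP60 library b they were -0.30 and -0.34.

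AluS elements, short retrotransposons without a protein of their own, were above 0 in 17 of 17 subfamilies, with a median of 0.27 that was 0.14 on the repeat-read scale and 0.16 after quantile normalization, and none passed singly (camera adjusted p = 3.18e-05, and adjusted p = 0.647 with an estimated correlation). Without the siTIP60 library a the AluS median was 0.15. AluY itself stood at 5370 ± 408 CPM in siControl and 6805 ± 1081 in siTIP60 (log2 change 0.33, adjusted p = 0.231). Of the 53 lists, 21 passed camera with the preset correlation, 12 upward and 9 downward. With the correlation estimated from 2 residual degrees of freedom, 0 passed, and 0 passed by fry (smallest adjusted p = 0.208).

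**Figure D2:**
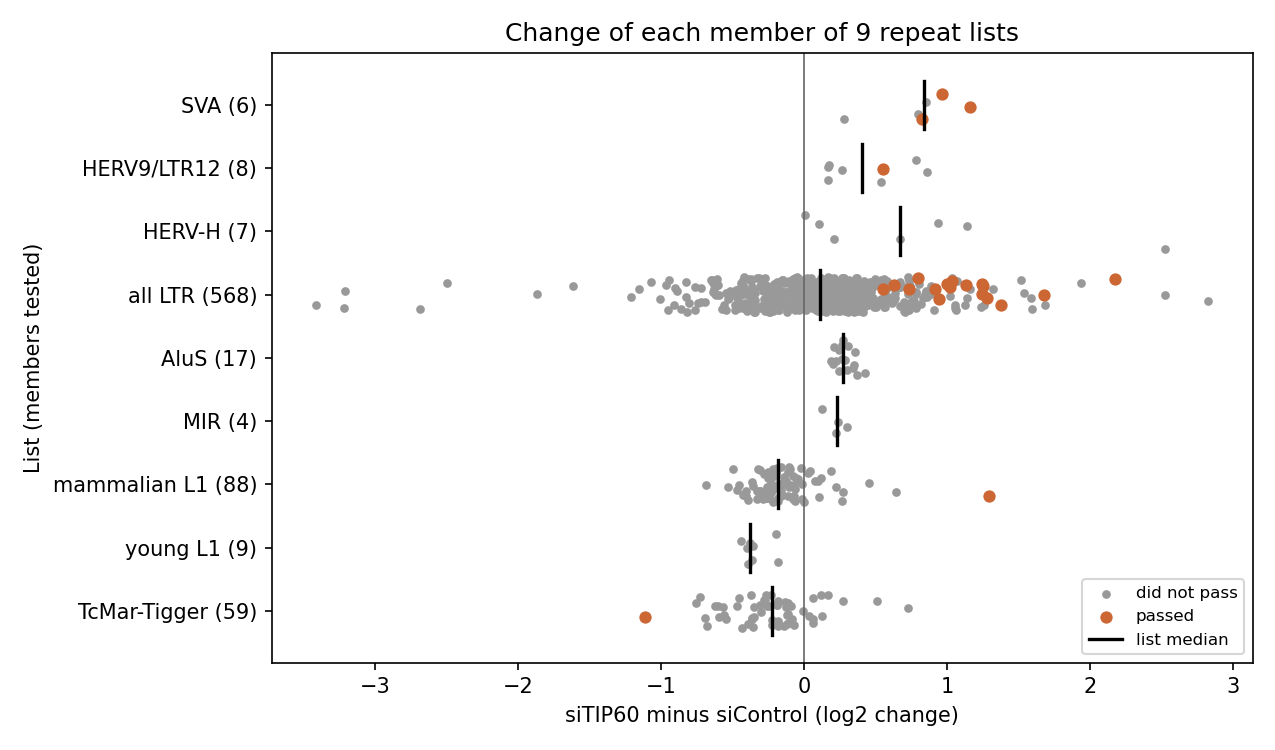
Log2 change, siTIP60 minus siControl (x axis), of each member of 9 repeat lists (y axis, number of members tested in parentheses). Orange points passed the test, grey points did not, and black ticks mark list medians, from 0.84 for SVA to -0.38 for young L1; the LTR median of 0.11 turned to -0.02 on the repeat-read scale.

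The authors' deposited table of fold changes gave a longer list for the same comparison. At a false discovery rate (FDR) under 0.05, the authors' deposited table called 51 subfamilies higher and 24 lower after TIP60 knockdown. Of the 51 in the authors' deposited table, 37 were LTR elements (72.5%, two-sided Fisher's exact p = 0.00243). Fisher's test again takes related subfamilies from the same libraries as independent. Its 24 lower subfamilies held 9 DNA transposons, 6 LTR elements and 5 LINE elements in the authors' deposited table. All 25 calls of the refit were among the 75 of the authors' deposited table, in the same direction, and the log2 changes of the refit and the authors' deposited table correlated at 0.950 across subfamilies, which are not independent replicates.

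The second comparison asked which subfamilies differed between JQ1 and DMSO. It rests on the authors' deposited table alone, because the 4 columns of values headed DMSO and JQ1 do not show which of them had the control siRNA and were not used here. Each JQ1 and DMSO condition has 1 sample, and which libraries the authors took as replicates for the FDR values is not known here. The direction is an assumption: the fold change in the authors' deposited table was taken as DMSO minus JQ1 from the order of the names. Were it JQ1 minus DMSO, every JQ1 sign given from the authors' deposited table would turn. On this assumption the authors' deposited table called 3 subfamilies higher in JQ1 and 0 lower, which are named here after their values were seen. They were LTR12D (log2 change 1.13, FDR 0.00670) and HERV9-int (0.85, FDR 0.00645), the terminal repeat and internal part of HERV9-type retroviruses, and HERVK13-int (0.95, FDR 0.0212). Of the 8 HERV9/LTR12 members in the authors' deposited table, 6 were above 0 under JQ1, with a median of 0.24, above 99.96% of 10000 random lists of the same size and level (0.04% with the sign turned). The young L1 median was -0.12, above 0.04% of such lists (99.96% with the sign turned), with 1 of 9 members above 0 in the authors' deposited table. The SVA median was -0.01, and 3 of its 6 members were above 0 in the authors' deposited table. Relatives can share reads and move together, which the random lists do not allow for, so these ranks can overstate how unusual a list was.

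The last comparison set the TIP60 knockdown beside JQ1. Across 1116 subfamilies of the authors' deposited table the changes under both correlated at 0.00881 (Pearson) and -0.00400 (Spearman). Over the 837 subfamilies left without those of lowest mean level, the values were 0.0519 and 0.0582. Only 3 subfamilies were called under JQ1, so most JQ1 changes may be noise, which draws a correlation towards 0. These values therefore do not show that the effects are unrelated. The 51 subfamilies that the authors' deposited table called higher after knockdown had a mean log2 change of -0.00403 ± 0.32 (SD across subfamilies) under JQ1, with 27 above 0 and 24 below. In the authors' deposited table their lowest JQ1 value was -1.23 for LTR58 and their highest 1.13 for LTR12D. LTR12D was the 1 subfamily called in both comparisons of the authors' deposited table. Whether the effects of knockdown and JQ1 differ was not tested for any subfamily.

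**Figure D3:**
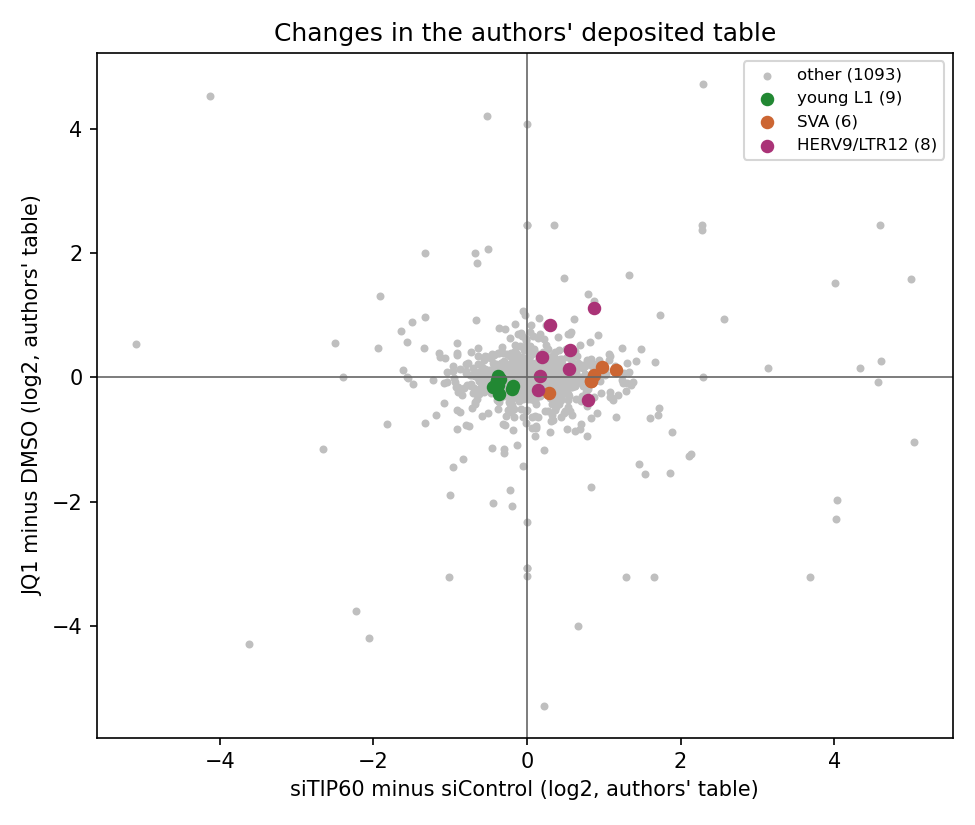
Log2 changes in the authors' deposited table for 1116 subfamilies, siTIP60 minus siControl on the x axis and JQ1 minus DMSO (direction assumed from the order of names) on the y axis, with SVA, young L1 and HERV9/LTR12 members coloured. SVA members lie to the right near a JQ1 change of 0, and LTR12D is the uppermost coloured point at 1.13.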

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

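The alternatives with voom weights, a term for ribosomal RNA and scaling to repeat reads were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate number, so the true pairing is unknown; the 2 pairings that can exist were each fitted through the term for ribosomal RNA. Fits using the DMSO and JQ1 columns were made with columns assigned by order and then withdrawn, since only 4 columns could be matched to samples, so none is reported. Between siTIP60 and siControl, 25 subfamilies passed, and all 25 kept their sign in each setting. Their groups do not overlap and several settings leave the changes as they are, so the signs could hardly have turned. The count was 7 with median centring and 9 with quantile normalization, all among the 25. It was 4 with a constant prior, none of them among the 25, and 46 with a robust prior, all 25 included. It was 35 without the lowest 25%, 24 with 1 added, 25 with the size condition and 29 with voom. With the ribosomal RNA term it was 195 (103 higher and 92 lower), and 69 with the siTIP60 libraries exchanged, all 25 included in each. These 2 fits have 1 residual degree of freedom and a prior of unlimited (195) or 289 degrees of freedom (69), so a subfamily's own spread hardly enters. Scaled to repeat reads without ribosomal RNA, which moved the median of all subfamilies to -0.12, 0 passed (smallest adjusted p = 0.0835, 242 at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 0 calls, with 1 residual degree of freedom fewer and the lone library taken to vary like the other group; at an unadjusted p under 0.05 there were 112 without siControl a, 108 without siControl b, 160 without siTIP60 a and 289 without siTIP60 b. Of the lists, 21 passed camera, 0 with a correlation estimated per list (smallest adjusted p = 0.647) and 0 by fry (smallest adjusted p = 0.208), and leaving out 1 library gave 12 to 22. The MaLR list, which did not pass (adjusted p = 0.778), turned upward in camera without the lowest 25% (adjusted p = 0.935) and without siTIP60 b; its median was also above 0 without siControl b (0.026). It had adjusted p of 0.270 to 0.721 over the libraries left out. MLT2A1 ranged from -0.18 to 0.0820 and HERV9-int from -0.0358 to 0.57 when 1 library was left out, and neither passed. The cause of these differences was not tested. The correlation of siTIP60 and JQ1 changes was 0.00881, and 0.0519 without the lowest 25% and -0.0215 with the refit's siTIP60 change. Noise in the JQ1 changes can hold each of these values near 0, so they do not show that the effects are unrelated. In simulation 33.3% of 1.5-fold changes were recovered, so depth and 2 libraries a group leave many changes of that size undetected.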

Other observations

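All tests of explanations in this part were chosen after the result was seen, except the count over other splits of the libraries.

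The hAT-Tip100 family of DNA transposons had a median log2 change of 0.22 after TIP60 knockdown, which was 0.086 when scaled to repeat reads without ribosomal RNA, with 25 of 31 members above 0 and Arthur1C past the test (camera adjusted p = 0.0122, and adjusted p = 0.647 with an estimated correlation). Without siTIP60 b its camera adjusted p was 0.0720. The DNA class, with 81 of 215 members above 0, had a median of -0.087, which was -0.22 on the repeat-read scale, and -0.14 without siControl a, -0.049 without siControl b, -0.024 without siTIP60 a and -0.17 without siTIP60 b (camera adjusted p = 0.00646, and adjusted p = 0.647 with an estimated correlation). The difference between the family and the rest of its class was not tested. In the authors' deposited table, the 6 centromeric satellite rows had a median log2 change of -1.03 under JQ1. Of these 6, 0 were above 0 and 0 were past an FDR of 0.05. The median lay above 0.02% of 10000 random lists drawn without regard to relatedness (99.98% with the assumed JQ1 sign turned).

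The count of 25 subfamilies was set against the other splits of the 4 libraries. Only 1 of the 3 splits, the real one, gave as many, and the highest of the others gave 0. With 3 splits a share under 0.05 cannot be reached.

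The higher values of SVA were weighed against 2 technical explanations, with each member set against its own larger difference between libraries of one group (median 0.37, largest 0.68), a bar adopted after the values were seen. Library scaling is argued against for SVA_B, SVA_C, SVA_D and SVA_E, as far as scalings set on repeat rows can show it. The list's median change stayed at 0.70 under the scaling that lowered it most. Ribosomal RNA content is argued against by order for the same 4: both siTIP60 libraries lie between the siControl libraries in ribosomal RNA, yet all 6 members were higher in both siTIP60 libraries, with a median gap of 0.63. In SVA_A the change (0.28) and the gap (0.063) lay within its own difference (0.33). In SVA_F the gap (0.44) lay within its own difference (0.68). Its change of 0.80 lay beyond that difference, but was 0.66 under the scaling that lowered it most. Both explanations stay open for SVA_A and SVA_F. Reads shared with genes or other repeats were not examined, and an effect of TIP60 loss, or of this 1 siRNA apart from its target, may underlie the higher values and was not tested.

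The lower values of young L1 were weighed in the same way, against a median difference of 0.17 within groups. The list's median change stayed at -0.36 under quantile normalization, which moved it towards 0. Median centring and repeat-read scaling moved it away from 0, to -0.40 and -0.51, so they could not test this. All 9 members' changes stayed beyond their own difference. In L1HS, L1PA2 and L1PA8A no scaling moved the change towards 0, so scaling was not tested for them. For the other members the changes argue against scaling, as far as quantile normalization of repeat rows can show it. By order, all 9 members were lower in both siTIP60 libraries, with a median gap of -0.26, which argues against ribosomal RNA content for the 6 members whose gap was beyond their own difference, in L1PA8 only just (-0.11 against 0.11). It stays open for L1HS, L1PA2 and L1PA6. An earlier bar, the levels' median, in effect 1 subfamily, had left all of young L1 open, and base composition was not examined, because no repeat sequences were used here.

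HERV-H may have missed the test because the libraries of a group differ along with ribosomal RNA. With a term for that difference 3 of the 7 members, LTR7, LTR7Y and HERVH-int, passed, against LTR7 and LTR7Y with the siTIP60 libraries exchanged. Both fits take their spread almost wholly from all subfamilies pooled, and exchanged, LTR7 differed by -0.14 in one pair and 2.01 in the other, so passing there is weak evidence. At the higher and lower level of ribosomal RNA these 3, picked because they passed, differed by 1.04 and 0.84 (LTR7), 1.26 and 1.02 (LTR7Y) and 0.90 and 0.45 (HERVH-int), while HERVH48-int (0.13 and -0.12) and LTR7B (0.26 and -0.060) went both ways. Fewer than the 4 members set for the explanation passed, the term was chosen from these data, and whether HERV-H responds to the knockdown stays open.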
